A study of Mus musculus with 26 samples.

How the data were processed

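RNA was measured in mouse MII oocytes (unfertilised eggs halted at the second meiotic metaphase) and in 1-cell embryos made by in vitro fertilisation from B6D2F1 parents. Per the labels' protocols, cells were lysed directly and libraries were made with the SMARTer Stranded Total RNA-Seq Pico Input kit, version 2. This kit amplifies very small amounts of total RNA. The titles number the libraries in 2 separate series. The first series holds 7 libraries of embryos treated with a c-Myc inhibitor and 7 of controls. The second holds 4 libraries of MII oocytes, 4 of control embryos and 4 of embryos treated with alpha-amanitin. The number of embryos or oocytes per library is not stated outright in the labels, so n counts libraries and SD is the spread between libraries. Per the labels' protocols, a thiazolidinone compound that disrupts the pairing of the transcription factor c-Myc with its partner Max was added 2 h after sperm and oocytes were mixed, for 10 h. It is called the c-Myc inhibitor here, and tables and sample titles carry its code name. Alpha-amanitin, a mushroom toxin that blocks RNA polymerase II, was used at 100 µg/ml from 1 h after mixing, for 10 h. The dose of the c-Myc inhibitor is not given in the sources used here. The labels give all embryos an age of 10 h, while the protocols' times add up to 12 h after mixing for the c-Myc inhibitor and 11 h for alpha-amanitin. The texts use the labels' age, and whether treated and control embryos were collected at 1 age was not tested.

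The authors deposited raw counts per gene, as whole numbers, in 1 table of 55401 Ensembl gene IDs by 26 libraries. Per the submitters' processing notes, reads were trimmed with cutadapt 1.7.1 and aligned with STAR 2.5.0a to GRCm38. The counting program, its strand setting and its annotation release are not given in the sources used here. Overlapping and antisense genes, and members of multigene families such as Duxf3, Zscan4, Usp17l and Obox, are therefore uncertain. Symbols and coordinates were taken from the GENCODE vM21 annotation of GRCm38. A symbol was found for 55141 IDs. The other 260 held 0.00563% of the counts. No count was present in any library for 21390 IDs.

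Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was the edgeR quasi-likelihood F test with TMM scaling, which corrects library totals for the few genes that take many counts. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The c-Myc inhibitor contrast used its own 14 libraries and 13003 genes. The contrasts of alpha-amanitin with its control, of control embryo with oocyte and of alpha-amanitin embryo with oocyte came from 1 fit of the other 12 libraries and 13133 genes. The difference of the inhibitors' effects was a contrast in 1 fit of the 22 embryo libraries and 15790 genes. Levels are CPM, each count scaled by its library's total, computed here with TMM-scaled totals where a log2 fold change stands beside them and with raw totals otherwise.

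A total of 26 gene lists were fixed: MYC targets, the MYC network, ribosome biogenesis factors, ribosomal proteins, translation factors, 2-cell-stage and minor genome activation genes, oocyte and maternal-effect genes, maternal mRNA decay machinery, replication-dependent histones, mitochondrially encoded mRNAs, Pol III and nuclear small RNAs, snoRNA host genes, RNA polymerase II and general transcription factors, the spliceosome, p53 targets, heat shock and chaperones, the unfolded protein and integrated stress response, immediate-early genes, G1/S and DNA replication, mitosis, DNA methylation and chromatin regulators, the proteasome, nuclear-encoded oxidative phosphorylation, glycolysis, cumulus and granulosa cell markers, and sperm and spermatid transcripts. The 25 lists with at least 5 measured members were tested with camera on voom values, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry. The sperm list was compared as a sum of CPM per library. Single values per library were compared with two-sided exact permutation tests, adjusted over 46 tests. The groups, tests, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined.

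The rule named, per contrast, the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM and group ranges that did not overlap, then the 3 members with the smallest p in each list that passed or had 3 or more called members, and 16 genes always reported where measured. Predicted genes were left out, and some genes that the rule names are not reported here. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were taken. Genes named outside this rule were chosen after their values were seen: Duxf3, Zfp352, Usp17ld, Usp17le, Tcstv1, Arg2, Gadd45g, Odf2 and the genes of the contrast of the inhibitors.

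The edgeR test was tested on simulated data with the real means, totals and spread and 200 changed genes of at least 10 CPM. For the c-Myc inhibitor the edgeR test recovered 84% of 2-fold and 99% of 4-fold changes, with 3.68% false calls. For alpha-amanitin it recovered 10% and 55%, with 1.52% false calls, and for embryo against oocyte 19% and 47%, with 2.94%. For alpha-amanitin embryo against oocyte it recovered 21% and 51%, with 4% false calls. For the difference of the inhibitors it recovered 21% and 61%, with 2.38%. The edgeR test made 0 calls in each of the 5 contrasts when nothing had been changed. In 1 simulation, camera with the preset correlation called the 1 shifted list and 0 of 24 others. The other tools were not tested on simulated data.

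The alternatives were other size factors, library totals alone, no filter or a filter at 10 CPM, DESeq2, limma voom with sample weights, a minimum fold of 2, leaving out mitochondrial genes, low-total libraries or each library in turn, only the groups compared, all 5 groups in 1 fit, a replicate term, camera with an estimated correlation, and fry. The fits with a replicate term, or replicate block, used only libraries whose number occurs in each group of their series. All 26 columns of the table were used. A zero count in a library limits a gene's level to 3 counts of that library's total, and over a group to 3 counts of the group's total. These floors cover counting error only.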

Results

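The data are RNA-seq counts from 26 libraries of mouse MII oocytes and 1-cell embryos. They address which transcripts change in the embryo's first hours, when it first transcribes its own genome, and what inhibitors of c-Myc and of RNA polymerase II do to them. The c-Myc inhibitor, a thiazolidinone compound, blocks the pairing of c-Myc with Max. Its series has 7 treated and 7 control embryo libraries with totals of 20566278 to 27266040 counts (median 23181826.5). The alpha-amanitin series has 4 oocyte, 4 control and 4 treated libraries with 5371602 to 31540627 counts (median 20030601). A count of 0 allows up to 0.11 to 0.146 CPM per library in the first series and 0.0951 to 0.558 CPM in the second. The median Spearman correlation between libraries of a group was 0.949 in the c-Myc inhibitor controls and 0.953 in the treated, but 0.930 in oocytes, 0.848 in alpha-amanitin controls and 0.831 in alpha-amanitin embryos. The biological coefficient of variation was 0.555 in the first series and 1.12 in the second. The labels name no donors or batches, so p-values measure the spread between these libraries.

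Under the c-Myc inhibitor, some transcripts of the oocyte, among them Gdf9, H1foo and Mos, were higher than in control embryos, while the list of such genes did not pass by camera. Gdf9, a growth factor made by oocytes (chromosome 11, 53431023 to 53437904, GRCm38), rose to 1957 ± 306 CPM from 412 ± 112 (SD, n = 7 each), a log2 fold change of 2.25 (SE 0.14, edgeR adjusted p = 4.8e-11). H1foo, the oocyte linker histone (chromosome 6, 115944938 to 115950236), rose by 1.66 on the log2 scale, and Mos, the kinase that holds the egg in meiotic arrest (chromosome 4, 3870657 to 3872105), by 2.06. Bub1b, a spindle checkpoint kinase (chromosome 2, 118598211 to 118641591), rose by 1.82, and Astl, the protease that cleaves the egg coat (chromosome 2, 127338639 to 127357651), by 1.59. In the list of oocyte and maternal-effect genes 9 of 52 measured members rose and 2 fell (11 and 5 adjusted over the list alone), with a list median of 0.02 (camera adjusted p = 0.101, fry adjusted p = 0.00104). That list also passed by camera with no filter on the genes, a setting chosen after the data were seen, but not on the filtered genes with an estimated correlation (adjusted p = 0.27). Among maternal mRNA decay genes 3 rose and 4 fell of 30 (3 and 6 adjusted over the list alone; camera adjusted p = 0.388). Dcp1a, a decapping factor (chromosome 14, 30479535 to 30527063), rose by 1.51 and Cnot8, a deadenylase, by 0.40, while Cnot6l, another deadenylase, fell by 0.33. Btg4, an adaptor of that deadenylase complex, was at 2100 CPM against 2036 and Zp3, an egg coat protein, at 47.8 against 39.5, and neither was called.

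Of 13003 genes tested, 887 were higher and 531 lower under the c-Myc inhibitor (edgeR quasi-likelihood, Benjamini-Hochberg), with 286 and 19 of them changed at least 2-fold. Among the largest rises by the rule were Taldo1, of the pentose phosphate pathway (log2 fold change 2.68; chromosome 7, 141392199 to 141402968), Foxred2 (2.60; chromosome 15, 77940522 to 77956722), Cers2, a ceramide synthase (2.54), Dse (2.44), Unc5a, a netrin receptor (2.40), and Akr7a5 (2.36). The largest falls were smaller: Got1, an aspartate aminotransferase (-1.07; chromosome 19, 43499752 to 43524605), Rnf115 (-0.90), Prdx1, a peroxiredoxin (-0.86; chromosome 4, 116685544 to 116700822), Ccar1 (-0.78), Napg (-0.75), Tubgcp5 (-0.75), Rbm7 (-0.72) and Ercc6l (-0.69). The higher genes held 10.3 ± 0.52% of counts in controls and 15.9 ± 0.86% in treated libraries (SD, n = 7 each), and the lower genes 15.7 ± 0.35% and 12.0 ± 0.59%. In 1 fit of all 5 groups the counts were 266 and 115, without Unc5a, Got1, Rnf115, Ccar1, Napg, Tubgcp5 and Ercc6l, and with DESeq2 859 genes were lower.

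**Figure D1:**
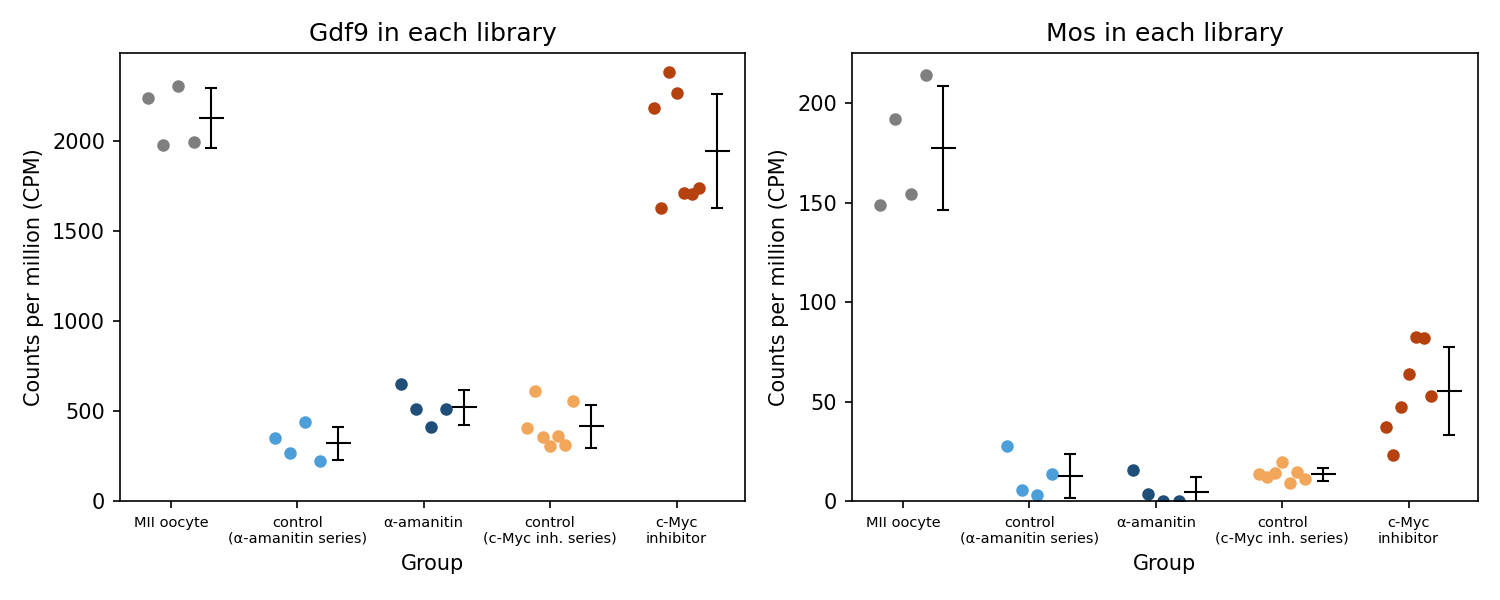
CPM of Gdf9 (left) and Mos (right) in the 5 groups, with 1 point per library and a bar at the mean ± SD. Gdf9 lay at 1627 to 2379 CPM in the c-Myc inhibitor libraries, above the 304 to 614 CPM of their controls.

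Transcripts of the drug's own target were near the floor. Myc had a mean of 0.109 ± 0.188 CPM in the controls, from 2 of 7 libraries, and 0 counts in all 7 treated libraries (up to 0.0180 CPM over the group). Mycn was at 0.189 ± 0.356 CPM in controls and likewise 0 in treated libraries. Max, the partner of Myc, was at 199 CPM against 198 (log2 fold change 0.01, edgeR adjusted p = 0.981). Of 54 MYC targets 7 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.737). Srm, a polyamine synthase, rose by 1.32, and Odc1, the first enzyme of that pathway, by 0.58. In the MYC network 4 of 16 rose and 0 fell (4 and 0 adjusted over the list alone), among them Mlx by 1.76 and Mxd1 by 0.42 (camera adjusted p = 0.0522, fry adjusted p = 6.0e-05). The MYC network also passed by camera with no filter, a setting chosen after the data were seen. It did not pass on the filtered genes by camera with an estimated correlation (adjusted p = 0.219). The calls of Srm, Odc1, Mlx and Mxd1 were lost in 1 fit of all 5 groups.

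The few ribosomal protein genes called under the c-Myc inhibitor were higher, and most of the ribosome-building factors called were lower. Of 74 ribosomal protein genes 4 rose and 0 fell (2 and 0 adjusted over the list alone), with Rpl41 up by 1.23 and Rplp0 by 0.76 (camera adjusted p = 0.00107; adjusted p = 0.356 with an estimated correlation). Of 53 ribosome biogenesis factors 10 fell and 1 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.00853; adjusted p = 0.0723 with an estimated correlation). Wdr75 was at -0.86, Bms1 at -0.42, the nucleolar protein Ncl (chromosome 1, 86344719 to 86359400) at -0.37 and Npm1, not called, at -0.03. In 1 fit of all 5 groups Rpl41, Rplp0, Wdr75 and Ncl lost their calls, and Ncl also with a replicate block. Heat shock and chaperone genes fell in 5 of 29 and rose in 0 (5 and 1 adjusted over the list alone), with Hsp90aa1, a main cytosolic chaperone (chromosome 12, 110690605 to 110702728), at 1968 against 3117 CPM (log2 -0.66) and its co-chaperone Dnaja1 at -0.62. That list had a camera adjusted p of 0.00853 (adjusted p = 0.219 with an estimated correlation). Unfolded protein and integrated stress response genes rose in 7 of 32 and fell in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00853; adjusted p = 0.219 with an estimated correlation). Slc3a2 and Slc7a11, the subunits of the cystine transporter, rose by 0.87 and 0.77.

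Mitosis genes fell in 7 of 48 and rose in 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00853; adjusted p = 0.263 with an estimated correlation). Ccnb1, cyclin B1, was at -0.56, whereas Bub1b and Espl1, the separase (0.81), rose. Spliceosome genes fell in 6 of 54 and rose in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0164; adjusted p = 0.311 with an estimated correlation), with Crnkl1 at -0.44 and Prpf8 at 0.64. Nuclear-encoded oxidative phosphorylation genes rose in 6 of 70 and fell in 1 (5 and 1 adjusted over the list alone), with Uqcrq at 1.49 (camera adjusted p = 0.0499; adjusted p = 0.571 with an estimated correlation). RNA polymerase II and general transcription factors fell in 7 of 52 and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0518). Tbp, the TATA-binding protein, was at -0.55. Hexim1, an inhibitor of the elongation kinase P-TEFb (chromosome 11, 103116231 to 103119725), went from 4.39 ± 3.09 CPM in controls to 0 counts in all 7 treated libraries, at least 243-fold lower by the floor over the group. It also had 0 counts in the 4 controls of the alpha-amanitin series, so the control level differed between the series. In 1 fit of all 5 groups Espl1 and Uqcrq lost their calls. So 7 of the 25 lists passed by camera with the preset correlation, 0 with an estimated correlation and 10 by fry.

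The remaining lists did not pass by camera under the c-Myc inhibitor. DNA methylation and chromatin regulators rose in 7 of 52 and fell in 7 (adjusted p = 0.293), with Trim28, a co-repressor, at 1.06, Uhrf1, a maintenance methylation factor, at 0.54 and Suz12, of Polycomb complex PRC2, at -0.44. Translation factors rose in 7 of 42 and fell in 5 (adjusted p = 0.647), with a median below 0 and a mean above it, and G1/S and DNA replication genes rose in 6 of 55 and fell in 4 (0.911). Glycolysis genes rose in 3 of 16 (0.107), replication-dependent histones in 2 of 32 (0.263) and p53 targets in 2 of 21 (0.737). Proteasome genes rose in 2 of 36 and fell in 1 (0.388), and 1 of 16 immediate-early genes fell (0.324). None of 6 Pol III and nuclear small RNAs (0.584), 5 snoRNA host genes (0.557) or 8 cumulus and granulosa markers (0.626; median above 0, mean below it) was called by edgeR. Mitochondrially encoded mRNAs fell in 3 of 10 and rose in 1 (0.388): mt-Nd5 and mt-Cytb were at -0.90 and -0.88, and mt-Nd6, on the other strand beside them, at 0.61. The call of mt-Cytb was lost in 10 of 14 fits with a library left out and with DESeq2, limma voom and a replicate block, that of mt-Nd5 with limma voom and in 1 fit of all 5 groups, and that of mt-Nd6 in that fit. Sperm and spermatid transcripts summed to 457 ± 75.3 CPM against 346 ± 43.1 (SD, n = 7 each; exact permutation p = 0.0035, adjusted p = 0.0375), mostly from Odf2 at 424 against 322 CPM. In unfertilised MII oocytes the sperm list summed to 279 CPM, with Odf2 at 217 CPM, so the sum includes RNA that is not from sperm. Cumulus markers summed to 235 against 244 CPM (exact permutation p = 0.624, n = 7 each).

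Some genes that the early embryonic genome switches on, among them Duxf3 and Zfp352, were lower under the c-Myc inhibitor, while the list of such genes did not pass by camera on the filtered genes. The 2-cell-stage and minor genome activation list had 3 members that fell and 1 that rose of 18 that passed the filter (4 and 1 adjusted over the list alone; camera adjusted p = 0.18, fry adjusted p = 0.0612). With no filter, a setting chosen after the data were seen, it passed (camera adjusted p = 0.00823), while on the filtered genes adjusted p = 0.334 with an estimated correlation. Many members lay below the filter, and each of the 39 with a count in this series was also compared by an exact permutation test, chosen after the data were seen. By mean 28 were lower and 11 higher, and 8 lower and 1 higher passed with p adjusted over the list alone. Duxf3, a copy of the activator Dux (chromosome 10, 58229979 to 58232675), had 4.27 ± 2.67 CPM in controls (range 0.216 to 8.05). It had 0 counts in all 7 treated libraries (exact permutation p = 0.000583, the smallest possible). By the control mean and the floor over the group, Duxf3 was at least 236-fold lower. In the alpha-amanitin series, only 2 of 4 control libraries had Duxf3 counts, at a mean of 1.84 CPM over the group. Zfp352 (chromosome 4, 90218820 to 90225702) went from 0.379 ± 0.463 CPM, with counts in 6 of 7 controls, to 0 (exact permutation p = 0.00466, n = 7 each). By the same measure Zfp352 was at least 21-fold lower. Usp17lc was at 0.615 against 5.94 CPM, and Usp17ld, Usp17le, Tcstv1, Arg2 and Zfp750 were also lower. Tcstv1, Arg2 and Zfp750 were already present in oocytes, at 16.1, 207 and 324 CPM, against 12.4, 136 and 380 CPM in these controls. Their lower levels therefore need not reflect less transcription by the embryo. Obox2, at 765 CPM in oocytes, was higher, at 558 against 392 CPM. The edgeR calls of Usp17lc and Obox2 were lost in 1 fit of all 5 groups. Klf17 (log2 fold change -0.10) and Zscan4d (-1.58) were not called by edgeR (adjusted p = 0.530 and 0.446). Over the 21 members without any oocyte count, the sum was 0.769 ± 0.889 CPM against 8.97 ± 4.60 (exact permutation p = 0.00117, n = 7 each). Genes nearly unique to 1 library also held less, 0.0116% of counts against 0.0272% (exact permutation adjusted p = 0.0134, n = 7 each). These families have near-identical copies, so the split of counts between members is uncertain.

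**Figure D2:**
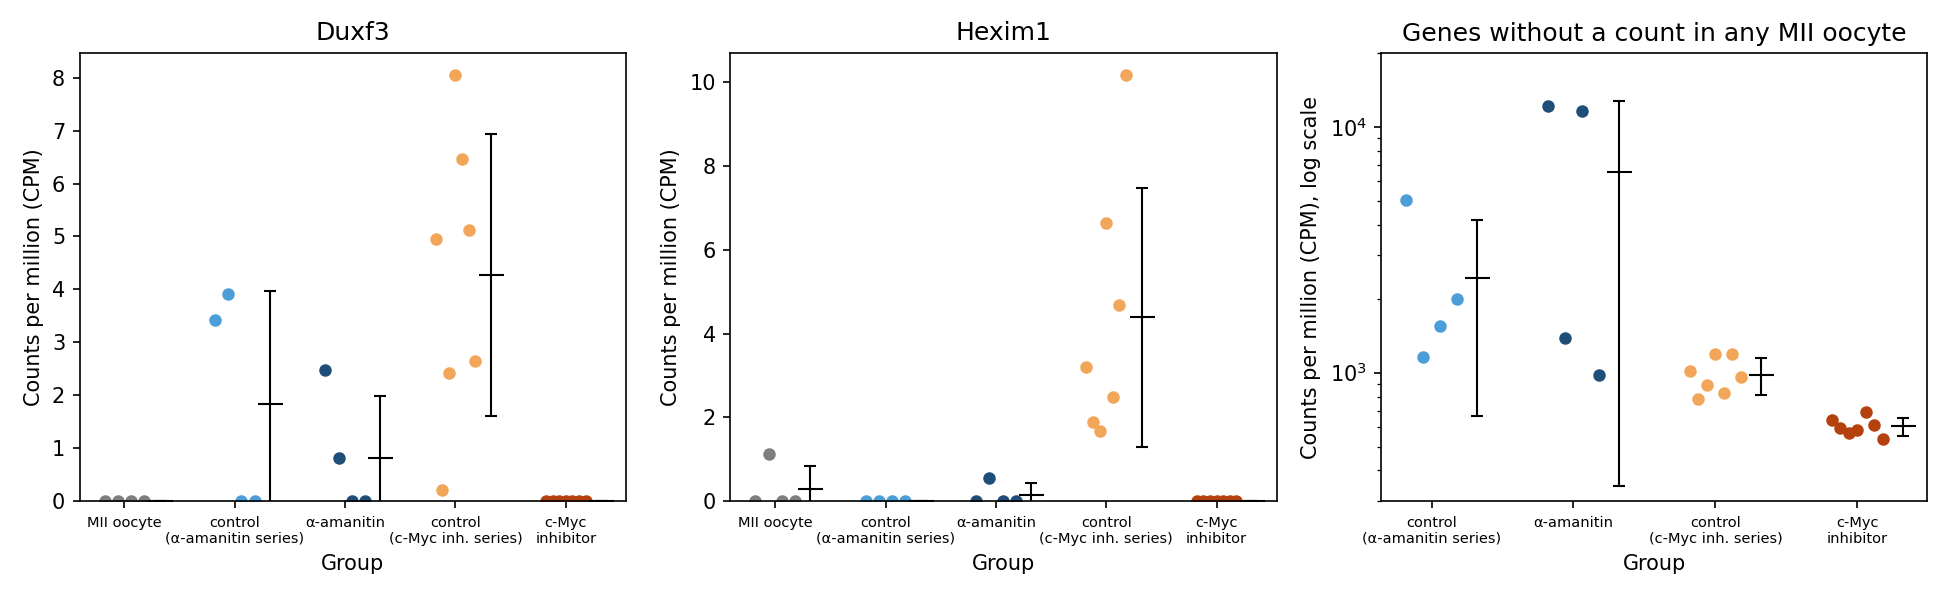
CPM of Duxf3, of Hexim1 and, on a log axis, of all genes without a count in any oocyte, with 1 point per library and a bar at the mean ± SD. Duxf3 had 0 counts in all 7 libraries of c-Myc inhibitor embryos and a mean of 4.27 CPM in their controls.

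Alpha-amanitin gave few calls. Tubb6, a beta-tubulin (chromosome 18, 67390717 to 67402749), rose to 233 ± 24.4 CPM from 104 (log2 fold change 1.17, SE 0.19, edgeR adjusted p = 0.0365, n = 4 each), and Nlrp14, a maternal-effect gene (chromosome 7, 107166990 to 107198102), to 684 from 282 CPM (1.28). Mgat4b, a glycosyltransferase (chromosome 11, 50210890 to 50235103), had 6.78 ± 4.22 CPM against 0 counts in all 4 controls, at least 169-fold higher by the floor over the group. The mitochondrial gene mt-Co1 (chromosome M, 5328 to 6872) fell to 1214 from 2317 CPM (log2 -0.93). Of 13133 genes tested 3 were higher and 1 lower by edgeR, with 986 at an unadjusted p under 0.05. If nothing had changed, a share of about 0.05 of the 13133 genes would also lie under that threshold. DESeq2 called 91 and 32, and each of the 4 calls was lost in 10 or 11 of the 12 fits with a library of this series left out.

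Gdf9 was at 518 against 328 CPM under alpha-amanitin (log2 fold change 0.66, edgeR adjusted p = 0.524) and was not called, nor were Klf17 (-0.19), Ncl (-0.07), Npm1 (-0.18) or Max (-0.10). By camera 3 of 25 lists passed, and 0 did with an estimated correlation or by fry. Mitochondrially encoded mRNAs had 1 of 8 lower (adjusted p = 6.26e-11; adjusted p = 0.185 with an estimated correlation). Ribosomal proteins were up with 0 of 74 called by edgeR (adjusted p = 0.0392; 0.671 with an estimated correlation), and chromatin regulators were down with 0 of 52 called (adjusted p = 0.0268; 0.671 with an estimated correlation). The activation list did not pass on the filtered genes (camera adjusted p = 0.172; adjusted p = 0.671 with an estimated correlation) and passed with no filter (camera adjusted p = 0.000535), a setting chosen after the data were seen. Of 34 activation genes with a count, 23 were lower and 11 higher by mean and 0 passed over the list, where the smallest p possible was 0.0286. Usp17lc was at 0.412 against 22.7 CPM and Zfp352 at 0.839 against 10.9. The sum over the 21 members without oocyte counts was 3.72 ± 5.32 CPM against 29.8 ± 20.6 (exact permutation p = 0.0571, n = 4 each), with a treated range of 0 to 11.3. Alpha-amanitin replicate 1, which had 12200 CPM in genes without a count in any oocyte, was the only treated library with Usp17lc or Usp17ld counts.

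Between the MII oocyte and the 10 h control embryo of the alpha-amanitin series, some oocyte transcripts, among them Gdf9 and Plat, fell and most mitochondrial mRNAs rose. Mitochondrial mRNAs held 0.443% of counts in oocytes and 1.10% in these embryos, but 0.446% in control embryos of the c-Myc inhibitor series. The control level of these mRNAs therefore differed between the series. Gdf9 fell to 328 ± 92.8 from 2122 CPM (log2 -2.70, SE 0.19, edgeR adjusted p = 6.49e-08, n = 4 each). Plat, tissue plasminogen activator (chromosome 8, 22757727 to 22782844), was at -2.63, Tle6, of the maternal subcortical complex (chromosome 10, 81590904 to 81601073), at -2.09, Zp3 at -2.09, Bub1b at -3.57 and March7 at -3.83. Mgat4b and Abhd17a went from 25.4 and 24.8 CPM to 0 counts in all 4 embryo libraries, at least 636-fold and 620-fold lower by the floor over the group. Rises were seen in mt-Nd4 (1.64), mt-Co1 (1.48), mt-Cytb (1.41), Snrpf, of the spliceosome core (1.86), Tnrc6a (1.42), Klf17 (0.93; chromosome 4, 117757836 to 117765648) and Hist1h1a, a linker histone (1.11; chromosome 13, 23763666 to 23764406). Emx2, a homeobox gene, rose to 125 from 22.1 CPM. The calls of Emx2 and Abhd17a were lost in 5 and 7 of 12 fits with a library left out. Mos, at -3.78, was not called in the main edgeR fit (edgeR adjusted p = 0.0569). In all, 146 genes were higher and 234 lower by edgeR, 29 and 200 of them at least 2-fold. Without alpha-amanitin replicates 1 and 3, which had 12200 and 11651 CPM in genes without a count in any oocyte, the counts were 250 and 403.

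By camera 9 of the 25 lists passed from oocyte to embryo, and 1 of them, mitochondrially encoded mRNAs, also did with an estimated correlation (6 of 8 rose, camera adjusted p = 2.35e-17, and 0.0429 with an estimated correlation). Those mRNAs held 0.446% of counts in control embryos of the c-Myc inhibitor series, near the 0.443% of oocytes. Oocyte genes fell in 13 of 52 and rose in 4 (adjusted p = 0.00679; 0.288 with an estimated correlation). Chromatin regulators rose in 7 of 52 and fell in 2 (adjusted p = 0.000149; 0.171 with an estimated correlation), with Zfp57, a keeper of imprints, at 0.83 and the histone gene H3f3b at 0.96. Ribosome biogenesis factors rose in 3 of 52 and fell in 2, with Npm1 at 0.77 and Wdr43 at 0.91 (adjusted p = 0.0248; 0.288 with an estimated correlation). Ribosomal proteins fell in 2 of 74 (adjusted p = 6.29e-08; 0.199 with an estimated correlation), oxidative phosphorylation genes in 1 of 74 (2.23e-08; 0.171) and stress response genes in 1 of 33 (0.00269; 0.199). Histones rose in 1 of 32 (0.0178; 0.549), and the activation list rose in 1 and fell in 1 of 22 (0.000394; 0.171).

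Embryos that developed in alpha-amanitin also differed from oocytes, with 58 genes higher and 167 lower by edgeR. On the log2 scale Gdf9 was at -2.04, H1foo at -1.97, Plat at -2.84, Bub1b at -2.91 and Mos at -5.13, all called lower. Surf6, a nucleolar protein, rose by 1.79, Wdr43 by 0.97, Klf17 by 0.74 and mt-Cytb by 1.02. The call of Surf6 was lost in 9 of 12 fits with a library left out, with a replicate block and without alpha-amanitin replicates 1 and 3, and that of Mos in 2 of 12. By camera 4 lists passed and 0 with an estimated correlation: ribosomal proteins were down (adjusted p = 9.65e-05; 0.573 with an estimated correlation), oxidative phosphorylation down (7.15e-07; 0.449), mitochondrially encoded mRNAs up (6.41e-10; 0.227) and the activation list up (0.0296; 0.573).

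The planned list of genes transcribed by 10 h, those that rose at least 2-fold from oocyte to embryo and fell at least 2-fold under alpha-amanitin, held 0 genes by edgeR and 0 by DESeq2. The alpha-amanitin contrast had 986 of 13133 genes at an unadjusted p under 0.05, where chance alone gives a share of about 0.05. With no minimum fold the list held only mt-Co1. Simulated unchanged groups on the same controls and the 6 splits of the controls also gave 0. The effect of the c-Myc inhibitor on such genes could not be tested.

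A comparison chosen after the data were seen set the c-Myc inhibitor effect beside the change from oocyte to embryo, which was measured in other libraries. Of the 200 genes that fell at least 2-fold from oocyte to embryo, 138 were higher and 4 lower under the c-Myc inhibitor, where independent lists would share 14.4 and 8.62. Gdf9, Bub1b and Dcp1a are among them. Their median log2 fold change was 0.84 (camera with an estimated correlation, adjusted p = 1.06e-05). Of the 146 genes that rose, 44 were lower and 0 higher, where 6.29 and 10.5 would be shared, with a median of -0.18 (adjusted p = 0.00387 with an estimated correlation). Of all genes higher under the c-Myc inhibitor, 86.9% were lower in the embryo than in the oocyte, against 51.9% of all genes.

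**Figure D3:**
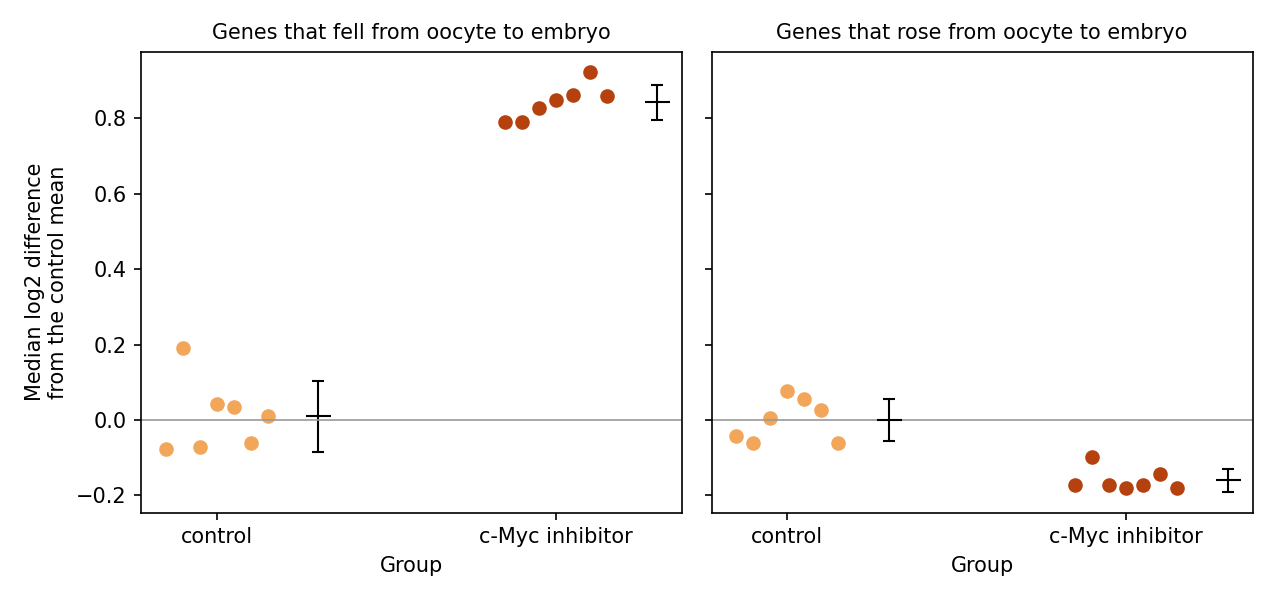
Median log2 difference from the mean of the controls, per library of the c-Myc inhibitor series, over genes that fell (left) or rose (right) from oocyte to embryo, with 1 point per library and a bar at the mean ± SD. Over the fallen genes the treated libraries lie at 0.79 to 0.92 and the controls at -0.08 to 0.19.

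**Figure D4:**
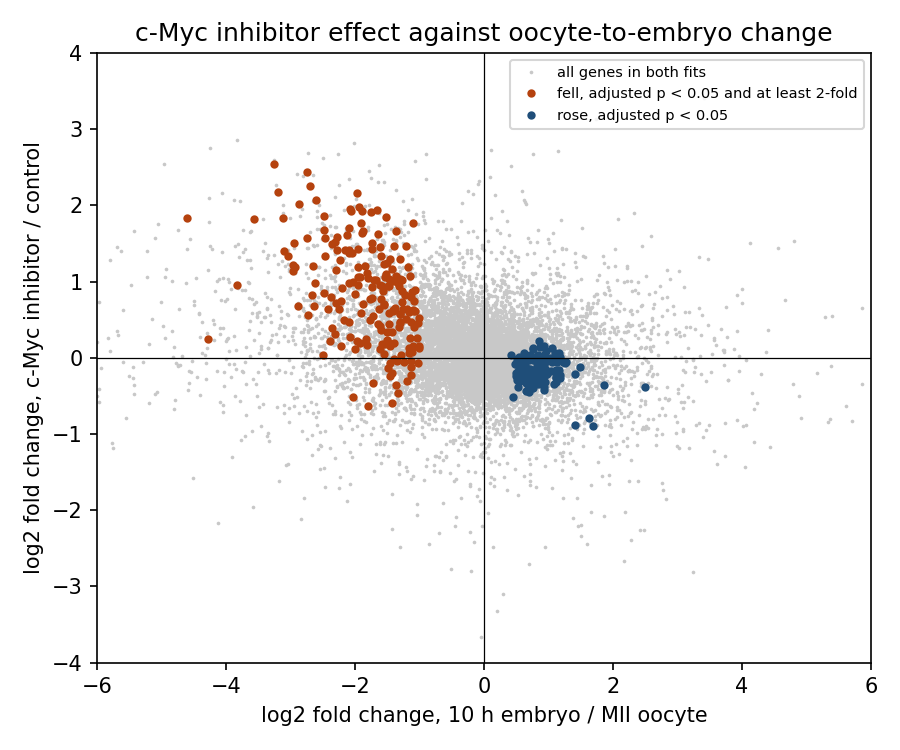
Log2 fold change under the c-Myc inhibitor against log2 fold change from oocyte to 10 h embryo, with 1 point per gene of 12280 and genes that fell or rose from oocyte to embryo in colour. The axes leave out 246 genes beyond 6 in size on the x axis or 4 on the y axis.

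The effects of the inhibitors were also compared directly. The difference was called for 165 of 15790 genes, 107 with a higher and 58 with a lower value under the c-Myc inhibitor (edgeR). H1foo differed by 1.77 on the log2 scale, Gdf9 by 1.60 and Dcp1a by 1.83 (edgeR adjusted p = 0.000404, 0.000493 and 0.00215). Of the 107 genes, 97 were themselves called higher under the c-Myc inhibitor and 46 had fallen from oocyte to embryo. With library totals alone 50.6% of the called differences were higher, against 64.8% with TMM, and the median of all genes was -0.104, against -0.0264 with TMM. The balance of directions also changed with the tool. Of the called differences, 39.6% of 1042 were higher with DESeq2, 90.9% of 33 with limma voom and 92.1% of 38 with a replicate block. Across 12280 genes, which are not independent replicates, the fold changes of the inhibitors had a Pearson r of 0.0301 and a Spearman rho of 0.0322 (permutation p = 0.168 from 100 reassignments of the labels). The alpha-amanitin fold changes come from a series with a biological coefficient of variation of 1.12. Such spread lowers a correlation, so these values do not show that the effects of the inhibitors are unrelated.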

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

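The tests of oocyte-like libraries, of a uniform delay, of depth, of scattered sequence, of the spread in the alpha-amanitin series and of alpha-amanitin replicates 1 and 3 were chosen after the results were seen.

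In 16 cases a library stood apart from the rest of its group. Over 30 measures 133 groups were tested. If values were normally distributed, chance would set a library apart in about 1 in 20, which is 6.65 here. Where only 1 library of a group has a count, the test always sets it apart. The expected number therefore does not hold for such groups, and the 16 cases show no excess over chance. Control replicate 2 of the c-Myc inhibitor series had 0.564% of counts in mitochondrial genes (others 1.72 to 2.47%) and Odc1 at 113.5 CPM (others 51.4 to 72.8). MII oocyte 3 had 0.290% in mitochondrial mRNAs (others 0.486 to 0.505%), and MII oocyte 4 had Odc1 at 42.7 CPM (others 76.4 to 81.4). Treated replicate 5 of the c-Myc inhibitor had 0.0185% of counts in genes nearly unique to it (others 0.00946 to 0.0117%). Myc was at 2.70 CPM in alpha-amanitin control 2 and 0 in the others, and Mycn at 0.973 CPM in c-Myc inhibitor control 6 (others 0 to 0.221). Btg4 was at 1818 CPM in c-Myc inhibitor control 8 (others 2024 to 2136), and Gadd45g at 8.56 CPM in control 6 (others 0.690 to 3.30). Hexim1 was at 1.13 CPM in MII oocyte 2 and 0.563 CPM in alpha-amanitin embryo 2, and 0 in the others of each group. Usp17lc was at 3.12 CPM in c-Myc inhibitor embryo 3 (others 0 to 0.588), 0.692 in MII oocyte 3 (others 0 to 0.0433) and 1.65 in alpha-amanitin embryo 1 (others 0). Usp17ld was at 0.287 CPM in c-Myc inhibitor embryo 3 and 4.69 CPM in alpha-amanitin embryo 1, and 0 in the others.

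The effects of the inhibitors differed, by a test of the difference, for 165 genes (edgeR). None of 99 other splits drawn reached that number, but the margin was narrow, since the highest gave 144. Many genes can thus be called by other splits too, so chance is not firmly excluded for the 165 calls. The log2 fold change under the c-Myc inhibitor minus that under alpha-amanitin was 1.77 for H1foo, 1.60 for Gdf9, 1.83 for Dcp1a, 2.61 for Dse, 0.95 for Slc7a11, 0.77 for Cnot8 and 1.51 for Astl. The fitted values of -8.14 for Mgat4b and -14.25 for Hexim1 rest on groups at 0 counts and give no size.

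Alpha-amanitin gave 4 calls. In counts simulated with the spread of its series, 10% of genes changed 2-fold were called, so the spread may account for few calls. Without alpha-amanitin replicates 1 and 3, which had 12200 and 11651 CPM in genes without oocyte counts, 3 genes were called. With 2 treated libraries left, whether those libraries hide changes cannot be told apart from the loss of libraries. The calls of higher genes were more than in any other of the 35 splits, by a narrow margin (3 against 1). With a replicate block, and with only the 2 groups compared, 0 genes were called, so chance is not firmly excluded for the higher genes. Nor can chance be excluded for the 1 lower gene (highest other split 1, seen in 2 of the 35 in all) or the 3 lists (7 of 35, highest other 5). For the 0 genes transcribed by 10 h the splits are no test, since any split gives at least 0 (35 of 35).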

How the results depend on the processing

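Leaving out alpha-amanitin replicates 1 and 3, the no-filter list tests and all settings for the lists of genes that fell or rose were chosen after the data were seen. No called value of a named gene changed sign, though values that were not called, such as Max under the c-Myc inhibitor, did. Of 2178 recomputed, 2000 kept their status as called or not called, 85 lost and 93 gained a call, and of 2784 with a library left out 2553 kept, 213 lost and 18 gained it. Of the 1418 calls under the c-Myc inhibitor, 1371 were kept with library totals alone, 1364 with RLE factors, 1402 with DESeq2 and 369 in 1 fit of all 5 groups. Where no construction is named, the cause was not tested.

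By setting, counts moved by over 1.5 times as follows. In 1 fit of all 5 groups, 266 genes were higher and 115 lower under the c-Myc inhibitor. A minimum fold of 2, which is stricter by construction, left 286 and 19 under the c-Myc inhibitor, 0 lower under alpha-amanitin, 29 higher from oocyte to embryo and 15 higher from oocyte to alpha-amanitin embryo. DESeq2 gave 859 lower under the c-Myc inhibitor, 91 and 32 under alpha-amanitin, 285 and 485 from oocyte to embryo, 204 and 312 from oocyte to alpha-amanitin embryo, and 1042 differences. Limma voom gave 6 lower under alpha-amanitin, 401 and 601, 328 and 578, and 33 differences. No filter gave 74 and 15 under alpha-amanitin, 186 and 286 from oocyte to alpha-amanitin embryo, and 443 differences. The filter at 10 CPM gave 227 and 110 higher from oocyte to embryo and to alpha-amanitin embryo. Without the low-total library, alpha-amanitin 3, 2 were lower under alpha-amanitin, 291 and 434 changed from oocyte to embryo, and 272 differed. Library totals alone gave 5 higher under alpha-amanitin, and leaving out mitochondrial genes, which removes mt-Co1, 0 lower. Only the 2 groups compared gave 0 and 0 under alpha-amanitin, and 293 and 471 from oocyte to embryo. Without alpha-amanitin replicates 1 and 3 these were 250 and 403. With an estimated correlation 0 lists passed for the c-Myc inhibitor, 0 for alpha-amanitin, 1 from oocyte to embryo and 0 to alpha-amanitin embryo. By fry 0 passed for alpha-amanitin, and without a filter 13 did, and 18 from oocyte to alpha-amanitin embryo. With no minimum fold 1 gene counted as transcribed, and the list of fallen genes had a median of 0.74.

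No pairing of libraries by replicate number was detected: correlations of same-numbered libraries were -0.031 to 0.049, and at most 1 pair per comparison correlated best with its own number. Such correlations cannot exclude that same-numbered libraries were handled together. With a replicate block, 292 genes were lower under the c-Myc inhibitor, 0 and 0 changed under alpha-amanitin, and 38 differed. In the c-Myc inhibitor series that fit kept only the 6 pairs of same-numbered libraries. The lower counts of that series and of the differences can therefore reflect fewer libraries as well as the block.

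With each library left out in turn, 762 to 901 genes were higher and 391 to 571 lower under the c-Myc inhibitor, 0 to 4 and 0 to 2 under alpha-amanitin, 63 to 291 and 146 to 434 from oocyte to embryo, 20 to 82 and 102 to 248 to alpha-amanitin embryo, and 92 to 272 differed. The correlation of the inhibitors was 0.00712 to 0.0425, transcribed genes 0 to 0, fallen genes 0.797 to 0.892 and risen genes -0.204 to -0.174. From oocyte to embryo the higher genes were 63, 70, 86 and 75 without oocytes 1 to 4, 78 and 86 without controls 2 and 4, and 291 without alpha-amanitin 3. The lower were 149 and 146 without oocytes 1 and 4, and 434 without alpha-amanitin 3. To alpha-amanitin embryo the higher were 21, 26, 26 and 20 without oocytes 1 to 4 and 36 without alpha-amanitin 1, and the lower 106, 107 and 102 without oocytes 1, 3 and 4. The differences were 107 without c-Myc inhibitor control 1, 92 without c-Myc inhibitor 7, and 252 and 272 without alpha-amanitin 2 and 3. No value could be had for low-total libraries in the c-Myc inhibitor series, which has none, for the correlation over genes called under alpha-amanitin, which are under 5, or for the c-Myc inhibitor on transcribed genes. Depth limits the alpha-amanitin series to 0.558 CPM in its smallest library.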

Other observations

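The lists of genes that fell or rose from oocyte to embryo, the genes without oocyte counts, the comparison of split libraries, and the tests of oocyte-like libraries, of a uniform delay, of depth and of scattered sequence were chosen after the results were seen. The form of the simulation of shared controls was also chosen after a first version, which picked its genes by rank, had been seen.

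Genes without a count in any of the 4 oocytes, 34827 in all, held 979 ± 165 CPM in controls of the c-Myc inhibitor series and 605 ± 50.4 CPM under the c-Myc inhibitor (SD, n = 7 each; exact permutation p = 0.000583, adjusted p = 0.0134 over 46 tests). In the alpha-amanitin series the genes without oocyte counts held 1156 to 5033 CPM in controls, 1390 CPM in alpha-amanitin replicate 2, less in replicate 4 and far more in replicates 1 and 3.

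Under alpha-amanitin the genes that fell from oocyte to embryo had a median log2 fold change of 0.28 and those that rose -0.21. These contrasts share their controls: simulated unchanged groups gave 0.15 and -0.18 (means of 20). Part of both values therefore comes from the shared controls. In 6 splits of the 4 controls, some controls chose the lists and the others gave the effect, so none was shared. These splits gave 0.05 to 0.20 and -0.20 to -0.07, over lists of 386 to 512 and 142 to 330 genes. The signs thus stayed without shared controls, at smaller sizes. The splits used lists other than those behind the main values and reuse the same libraries.

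For the rise under the c-Myc inhibitor of genes that fall from oocyte to embryo, no other of the 100 splits gave as many higher genes (887; highest other 5), lower genes (531; highest other 5), or as large a median of the fallen genes (0.84; highest other 0.58) or the risen genes (0.18 in size; highest other 0.15), so chance can be excluded for each of these, and only narrowly for the 7 lists (3 of 100 gave as many; highest other 8), of which 0 passed with an estimated correlation. The lowest treated library had a median of 0.79 over the fallen genes, above all controls, which argues against a few oocyte-like libraries among the treated. Lists matched on GC content, transcript length and expression reached 0.0121 at the upper end of their central 95%, which argues against those properties. With lists and folds from separate parts of the libraries, the share of the change not made was 51.6% for fallen and 27.2% for risen genes. Each is a median over 36 splits. Within a split the shares differed by a median of 26.0 points, with 13.5 points near the low end. The splits reuse the same libraries, so their spread is no interval for the difference. The change itself was measured with controls of the alpha-amanitin series, whose levels can differ from the c-Myc inhibitor controls (Klf17 at 1126 against 911 CPM). The difference argues against 1 uniform delay only if the change was alike in both series, which was not tested. A candidate explanation is that the c-Myc inhibitor slows the fall of the fallen genes more than the rise of the risen ones. This hypothesis was found and tested on the same data, while effects of the drug outside c-Myc and of the handling of the groups stay untested. The risen genes are not shown to be newly transcribed. Of those 146 genes, 1 was called lower under alpha-amanitin, in a contrast that recovered 10% of simulated 2-fold changes.

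The lower level of genes without oocyte counts under the c-Myc inhibitor may reflect less early transcription or less scattered sequence. With every library thinned to 1 total, such genes with a count were 1056 against 1511 (exact permutation p = 0.00117, n = 7 each). Treated libraries had the higher mean total before thinning (23785000 against 22870600 counts), so thinning was no test of depth, and the totals themselves argue against lower depth in the treated. Genes seen in fewer than 6 of the 7 controls made up 89.5% of the excess, and genes nearly unique to 1 library also held less in the treated (0.0116% of counts against 0.0272%). Genomic DNA or other scattered sequence in the controls predicts this, and so does scattered early transcription, so these cannot be told apart.

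For the contrasts with oocytes, no other of the 35 splits gave any called gene in either direction (highest other 0). The real counts were 146 and 234 for control embryos and 58 and 167 for alpha-amanitin embryos, so chance can be excluded for these counts. For control embryos no other split gave as many lists, but the margin was narrow (9, highest other 7). With an estimated correlation 1 of those lists passed, so chance is not firmly excluded for them. For the 4 lists of alpha-amanitin embryos chance cannot be excluded (7 of 35 splits; highest other 4).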
